A study of mixed DNA library with 12 samples.

How the data were processed

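The assay, Coop-seq, mixes 2 DNA-binding proteins with a pool of DNA molecules that share fixed ends and differ in a short randomised stretch, and separates the mixture on a native gel so that free DNA, DNA with 1 protein and DNA with both proteins run as separate bands. Per the labels' protocols, 200 nM of a 109 amino acid construct of the Sox2 HMG domain and 300 nM of the Pax6 paired domain were mixed with 250 nM of the library and run on a 12% polyacrylamide gel. The dimer, monomer and free DNA bands were cut out, the eluted DNA was amplified by PCR with barcoded primers, and the products were sequenced with 125 bp reads. The series holds 1 experiment with 3 technical replicates of each of the 4 bands, 12 libraries in all. The labels' descriptions of 4 samples speak of raw data from 5 replicates and those of 2 samples of 2 replicates, against 3 in the series design and in the deposited counts. What these numbers refer to is not given in the sources used here, so it is open whether each of the 3 replicates is a single reaction. The p-values of edgeR and limma below therefore measure the spread between technical replicates only.

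The authors deposited read counts for each of the 1024 possible sequences of 5 bases in the 4 bands of each replicate, per the labels and the file headers. How reads were filtered, trimmed and assigned to a sequence is not given in the sources used here, and neither is the use of molecular identifiers, so PCR copies are counted as reads. The authors also deposited a cooperativity ratio for each replicate, which the deposited description defines as dimer count times free count over the product of the Sox2 and Pax6 monomer counts. It further holds the median ratio of each replicate, the ratio divided by that median, and the mean and SD of the divided ratio over replicates. Recomputed from the counts, the deposited ratios differed by at most 5.0e-14. The place of the 5 bases in the oligonucleotide, their strand and the fixed flanking bases are not given in the sources used here, and positions are counted from 1 at the 5′ end of the deposited sequence. No column was left without a sample.

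Total reads per library ran from 271782 in the Pax6 monomer band of replicate 3 to 1688530 in the unbound band of replicate 1. The lowest count of any sequence in any library was 24, so no value rests on a count of 0. The chi-square statistic of 2 replicates of a band over its degrees of freedom, which counting error alone would bring to about 1, lay between 1.48 and 10.4 for all 12 pairs, and no library was counted as a copy of another.

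Counts were compared with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F-test after TMM normalisation, with the 12 libraries in one fit and one term per band. Sequences needed at least 10 reads in at least 3 libraries, and all 1024 passed. Each sequence was tested in 6 contrasts: each of the 3 bound bands against unbound DNA, the dimer against each monomer, and cooperativity, which is the log2 ratio of dimer times unbound over the product of both monomers. P-values were adjusted by the Benjamini-Hochberg method within a contrast, at a threshold of 0.05. Band totals were not measured, so every log2 value is relative to the typical sequence of the library. The log2 value per replicate was taken from normalised counts of the 4 libraries with that replicate number, and means and SDs are over 3 such values. Per the deposited description, a replicate number covers the 4 bands of 1 technical replicate, in which the authors' ratio is computed, and the numbers are taken to pair the libraries, which was decided after the fits with and without the block had been seen. Whether the bands came from the same gel lane is not given in the sources used here. Deviations of same-numbered libraries from their band means correlated at 0.24 to 0.31 for replicate 1 and at -0.02 to 0.31 over all 18 pairs, with 10 pairs above 0.1.

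The contribution of each base was estimated per library by regressing the log2 share of reads, with a pseudocount of 0.5, on the base at each of the 5 positions, with coefficients that sum to 0 within a position. The 20 coefficients were compared between bands with limma 3.58.1 and adjusted within each contrast. For chosen pairs of bases, 14 differences were tested in the same way, chosen after the coefficients had been seen. Adjusted R2 was computed across sequences for a model of single bases and for one with adjacent dinucleotides added. Enrichment of a base among the 10 highest or lowest sequences was tested with a one-sided Fisher's exact test over 240 combinations. Its p-values hold no replicate spread and treat sequences as independent draws, though sequences that share bases are not independent. Groups of sequences fixed before the data were examined were tested with camera at a preset correlation of 0.01. Camera's p-values also rest on that correlation between sequences. The groups are sequences with at least 1 CpG, with a G+C content of 60% or more and with 40% or less. The motifs CACGC and TCACC and their reverse complements have too few members for a group test and are given as single values, and longer Sox2 and Pax6 motifs cannot occur in 5 bases.

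Named sequences follow a rule set before the data were examined: for each contrast, the 10 highest and 10 lowest log2 values among sequences past the threshold, with a mean of at least 100 reads per library and the same direction in all 3 replicates. At least the first 3 of each end are named with values.

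The fits were tested on simulated counts, set up after the first results had been seen and drawn from the means, library sizes and dispersions of these libraries, with 200 of 1024 sequences changed in the compared band. For cooperativity, 29.9% of changes of log2 0.25, 80.6% of log2 0.50 and 100% of log2 1.00 were called, with 6 false calls. For Sox2 monomer over unbound DNA, 67.2% of changes of log2 0.25 were called, with 7 false calls. The unchanged sequences had the same mean share in every simulated band, while edgeR called 53.5% to 91.9% of the real sequences in a contrast. These rates therefore need not hold for the real data, where most sequences were called. All 20 of 20 simulated base coefficients of cooperativity were called, with a largest error of 0.016. The simulated noise was independent between sequences, while the real cooperativity coefficients had replicate SDs of up to 0.12, so the real error can be larger. All 20 were simulated as changed, so that contrast says nothing about false calls. Alternatives were the normalisation, the test tool (DESeq2 1.42.0), the filter, a test against a 2-fold change, the libraries in the fit, the replicate number as a block, the pseudocount, weights and leaving out each replicate. Thinning of all libraries to the smallest total and the removal of TCCTC and ATGCT were added after the data had been seen. Figures were drawn with matplotlib 3.10.9.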

Results

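The data describe how 2 developmental transcription factors, Sox2 and Pax6, distribute over DNA that differs only in 5 bases. Sox2 carries an HMG domain, which binds the minor groove and bends DNA, and Pax6 carries a paired domain, which contacts DNA through a pair of helical subdomains. The series title asks whether Sox2 changes the sequences that Pax6 recognises. Read counts were available for 1024 sequences in 4 gel bands, each with 3 technical replicates: unbound DNA, Sox2 monomer, Pax6 monomer and Sox2-Pax6 dimer. Both proteins were present in the reaction, so Sox2 alone and Pax6 alone below mean DNA that ran with only that protein bound. In total 8669583 reads were counted. The unbound libraries held 1688530, 697771 and 591571 reads, the Sox2 monomer libraries 818512, 408126 and 424529, the Pax6 monomer libraries 778250, 384923 and 271782, and the dimer libraries 1445514, 636694 and 523381.

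Replicates of a band were alike in their sequence shares. The correlation of log2 normalised counts across sequences between replicates of a band lay between 0.978 and 0.994. For the log2 ratios it was lowest for Sox2 monomer over unbound DNA, at 0.857, and at least 0.954 for the other 5 contrasts. The median SD of a sequence's log2 ratio between replicates was 0.09 for Sox2 monomer over unbound DNA, 0.11 for Pax6 monomer over unbound DNA and 0.17 for cooperativity.

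Sox2 on its own distinguished little between the sequences. The ratio of Sox2 monomer to unbound DNA spanned 4.99-fold over the 1024 sequences, against 35.0-fold for Pax6 monomer and 74.9-fold for the dimer. The sequences most enriched with Sox2 were TGGTT, at a log2 ratio of 1.02 (replicate SD 0.07, n = 3), TGGGA at 1.02 (SD 0.07) and TGCTT at 1.00 (SD 0.20), with edgeR adjusted p-values of 5.5e-10, 1.5e-09 and 3.9e-09. The most depleted were GCTCG at -1.30 (SD 0.05), GCTGA at -1.25 (SD 0.30) and GCTCC at -1.20 (SD 0.20). All of the 10 highest sequences began with T (Fisher's exact test, adjusted p = 1.7e-05) and 9 had G at position 2 (adjusted p = 0.00046). Among the 10 lowest, 8 began with G and 8 had T at position 3 (adjusted p = 0.0052 for each). The fifth of the highest, TCCTC, had a log2 ratio of 0.98, but its read counts stood far above those of its neighbouring sequences in each of the 12 libraries.

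Position 1 carried the widest range of base coefficients for Sox2. T at position 1 raised the log2 ratio by 0.30 (replicate SD 0.01, n = 3, limma adjusted p = 3.2e-05) and G lowered it, with a coefficient of -0.29 (SD 0.0044, adjusted p = 1.1e-08). At position 2, G had the most positive coefficient, 0.20, and C the most negative, -0.19. At position 3, G stood at 0.18 and T at -0.22, and at position 4, T at 0.10 and C at -0.10. At position 5, T stood at 0.12 (adjusted p = 0.0093) and G at -0.084 (adjusted p = 0.038), while C, the most negative at -0.094, did not pass (adjusted p = 0.092). Of all sequences, 276 were higher and 272 lower than in unbound DNA in edgeR's test, and 13 of 20 base coefficients passed in limma, or 16 with the replicate number as a block. The counts of sequences fell to 156 higher and 163 lower without replicate 1, and 2 of the higher and 7 of the lower sequences had changes of 2-fold or more.

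Pax6 alone favoured sequences that end in GCT. The highest ratios of Pax6 monomer to unbound DNA belonged to CTGCT, at a log2 value of 3.65 (SD 0.27, n = 3), a 12.6-fold enrichment, GTGCT at 3.48 (SD 0.21) and TTGCT at 3.28 (SD 0.14). The corresponding edgeR adjusted p-values were 1.2e-16, 1.2e-16 and 6.1e-17. Of the 10 highest sequences, all had G at position 3 and T at position 5 (Fisher's exact test, adjusted p = 1.7e-05 for each) and 8 had C at position 4 (adjusted p = 0.0052). The lowest ratios belonged to GGAAA at -1.48 (SD 0.15), TACAA at -1.35 (SD 0.08) and CCAAA at -1.33 (SD 0.05), and all of the 10 lowest ended in AA (adjusted p = 1.7e-05 for each A).

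The base coefficients of Pax6 alone had the widest range at position 5. T was most favoured there, at 0.46 (SD 0.06, limma adjusted p = 3.4e-07), followed by C at 0.18 (SD 0.04), while A was most disfavoured, at -0.51 (SD 0.03). G led at position 3, at 0.37 (SD 0.03), against C at -0.33 (SD 0.0044). At position 4, G was the most favoured base at 0.22 and T the least at -0.27. T at position 2 stood at 0.25 and G at -0.20, and at position 1 C stood at 0.15 and T at -0.16. Single-base effects described Pax6 alone less fully than the other contrasts, with an adjusted R2 of 57.2% against 75.5% to 89.3%, and adding adjacent dinucleotides raised it to 73.3%. The largest gains from a single pair of positions were 7.68 percentage points for positions 3 and 4 and 7.36 points for positions 3 and 5. Of all sequences, 350 were higher and 399 lower in edgeR's test. With library totals in place of TMM the split was 254 higher and 509 lower, so the share of higher calls moved from 46.7% to 33.3%. In limma 18 of 20 base coefficients passed, from a fit that does not use TMM and so could not change with it.

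The dimer band was most enriched over unbound DNA for TCTGC, at a log2 ratio of 3.34 (SD 0.21, n = 3), TCCGC at 3.19 (SD 0.19) and TTTGC at 3.17 (SD 0.34), with edgeR adjusted p-values of 6.6e-17, 5.4e-17 and 4.4e-17. It was most depleted for AGCAA at -2.89 (SD 0.06), CGCAA at -2.70 (SD 0.24) and CGGAA at -2.64 (SD 0.22). All of the 10 highest began with T and 9 ended in C (Fisher's exact test, adjusted p = 1.7e-05 and 0.00046), and all of the 10 lowest had G at position 2 and A at position 5 (adjusted p = 1.7e-05 for each). By position, the most favoured base was T at position 1 (0.95), T at position 2 (0.53), T at position 3 (0.33), C at position 4 (0.30) and C at position 5 (1.08). The most disfavoured was A at position 1 (-0.40), G at position 2 (-0.68), A at position 3 (-0.28), T at position 4 (-0.40) and A at position 5 (-1.16). Higher and lower sequences numbered 469 and 460 in edgeR's test, and 240 and 261 of these changed by 2-fold or more.

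The ratio of dimer to Sox2 monomer compares DNA with and without Pax6 where Sox2 is present. It was highest for TTTGC, at a log2 value of 3.56 (SD 0.34, n = 3), TTTCC at 3.50 (SD 0.57) and TCTGC at 3.49 (SD 0.42), and lowest for AGCAA at -3.03 (SD 0.10), CGGAA at -2.93 (SD 0.10) and CGCAA at -2.91 (SD 0.19), with edgeR adjusted p-values of at most 4.9e-16. All of the 10 highest began with T (Fisher's exact test, adjusted p = 1.7e-05), and 7 each had T at position 3 and C at position 5 (adjusted p = 0.033 for each). All of the 10 lowest ended in A (adjusted p = 1.7e-05), and 8 had G at position 2 (adjusted p = 0.0052). The range of 96.6-fold over the sequences was the widest of the 6 contrasts. The position with the widest range of coefficients was again position 5, where C stood at 1.17 (SD 0.12), G at 0.72 (SD 0.06), T at -0.67 (SD 0.05) and A at -1.22 (SD 0.12). At position 2, T stood at 0.68 (SD 0.02) and G at -0.88 (SD 0.03). At positions 1, 3 and 4 the most favoured bases were T at 0.65, T at 0.55 and C at 0.40, and the most disfavoured A at -0.43, A at -0.34 and T at -0.51. In edgeR's test 463 sequences were higher and 475 lower. G at position 1 (0.021) did not pass in limma (adjusted p = 0.15) and passed with the replicate number as a block (adjusted p = 0.021).

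The ratio of dimer to Pax6 monomer compares DNA with and without Sox2 where Pax6 is present. TCCGC was highest, at a log2 value of 3.01 (SD 0.20, n = 3), followed by TACCC at 2.99 (SD 0.12) and TTCCG at 2.95 (SD 0.09). CGTAA was lowest at -2.69 (SD 0.01), followed by CGTGA at -2.60 (SD 0.09) and AGTAA at -2.52 (SD 0.05), and the edgeR adjusted p-values of these 6 sequences were at most 1.4e-15. T at position 1 had a coefficient of 1.12 (SD 0.06), the most positive of the 20, and T at position 5 had the most negative, -1.01 (SD 0.07, limma adjusted p = 1.5e-10 for both). C was most favoured at position 5 (0.90), at position 2 (0.33), at position 3 (0.24) and at position 4 (0.10). The most disfavoured bases were C at position 1 (-0.43), G at position 2 (-0.48), G at position 3 (-0.34) and T at position 4 (-0.13). Of the 10 highest sequences, all began with T (adjusted p = 1.7e-05 in Fisher's exact test) and 7 ended in C (adjusted p = 0.033). In edgeR's test 477 sequences were higher and 464 lower.

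Cooperativity, the ratio that asks whether both proteins share a DNA molecule more often than their separate binding implies, was highest for TCTCG, TATCC and TTTCG. Their log2 values were 3.34 (SD 0.22, n = 3), 3.34 (SD 0.64) and 3.31 (SD 0.22), about 10.1-fold, 10.1-fold and 9.90-fold above the typical sequence, with edgeR adjusted p-values of 1.2e-14, 4.5e-13 and 3.7e-15. The lowest were CGTAA at -2.85 (SD 0.26), AAGCT at -2.64 (SD 0.15) and AGTAA at -2.61 (SD 0.12). AAGCT was also among the 10 sequences most enriched with Pax6 alone, where its log2 ratio was 3.18 (SD 0.23). Cooperativity subtracts that ratio, so the low value of AAGCT was partly built in. All of the 10 highest began with T (Fisher's exact test, adjusted p = 1.7e-05) and 7 had C at position 4 (adjusted p = 0.033). Cooperativity was higher for 447 sequences and lower for 459 in edgeR's test, with 252 and 299 of them by 2-fold or more. In the authors' deposited table the mean normalised ratio ran from 0.142 to 11.4, an 80.1-fold range, and TATCC ranked highest.

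**Figure D1:**
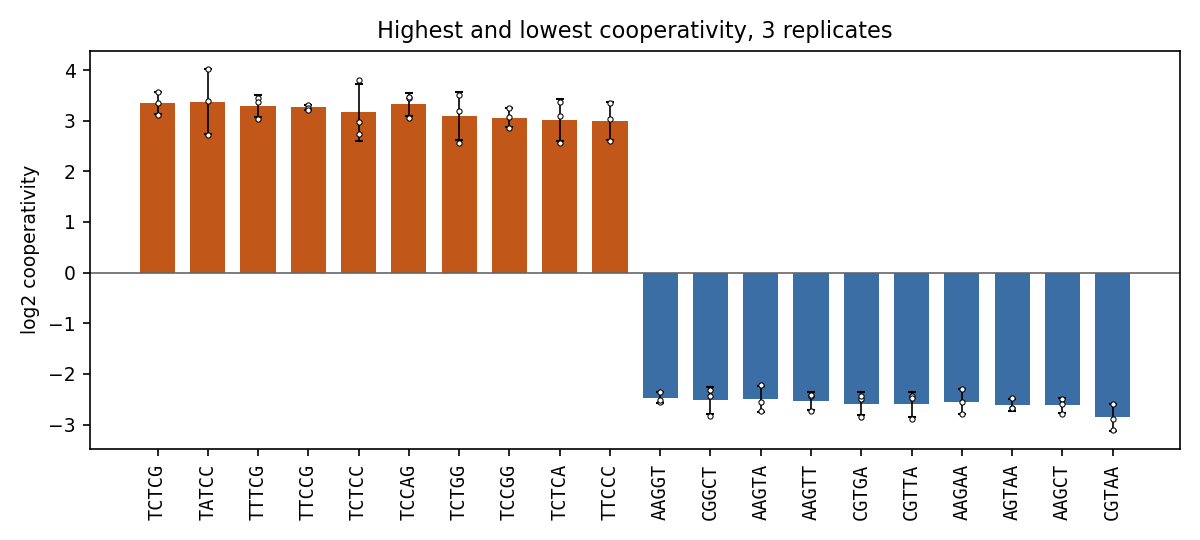
Log2 cooperativity (y axis) of the 10 highest and 10 lowest sequences (x axis), relative to the typical sequence. Bars are means, error bars SDs and circles the 3 replicates. TATCC has a replicate SD of 0.64 and CGTAA one of 0.26.

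The base coefficients of the ratios of DNA with to DNA without Pax6 differed by whether Sox2 was present. At position 5 the difference between C and T was -0.28 (replicate SD 0.10, n = 3) for Pax6 alone, so T was the more favoured. It was 1.84 (SD 0.17) in dimer over Sox2 monomer, where C was the more favoured. Both are averages over sequences and need not hold for each. The 16 sequences ending in GCT had a mean log2 ratio of 2.81 for Pax6 alone, where the model of single bases gave 1.07. In dimer over Sox2 monomer their mean was 0.82, where that model gave -0.41. The change in C minus T of 2.12 (SD 0.19), a 4.36-fold shift, passed limma's test of the cooperativity contrast at an adjusted p of 2.1e-09. The same contrast compares the Sox2 ratios with and without Pax6, so it cannot assign the change to 1 of the proteins. Read that way, C minus T at position 5 was -0.22 (SD 0.02) in Sox2 monomer over unbound DNA. It was 1.91 (SD 0.19) in dimer over Pax6 monomer. The 5 largest coefficients of the cooperativity contrast were T at position 5 (-1.13, SD 0.07), C at position 5 (0.99, SD 0.12), G at position 5 (0.85, SD 0.05), T at position 1 (0.82, SD 0.05) and A at position 5 (-0.71, SD 0.12). By position, the highest coefficients of the other positions were C at position 2 (0.52), T at position 3 (0.43) and C at position 4 (0.20). The lowest were A at position 1 (-0.45), G at position 2 (-0.68), G at position 3 (-0.52) and T at position 4 (-0.23). In all, 19 of 20 coefficients passed, and G at position 1 did not (0.027, limma adjusted p = 0.20), except with the replicate number as a block (adjusted p = 0.035).

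**Figure D2:**
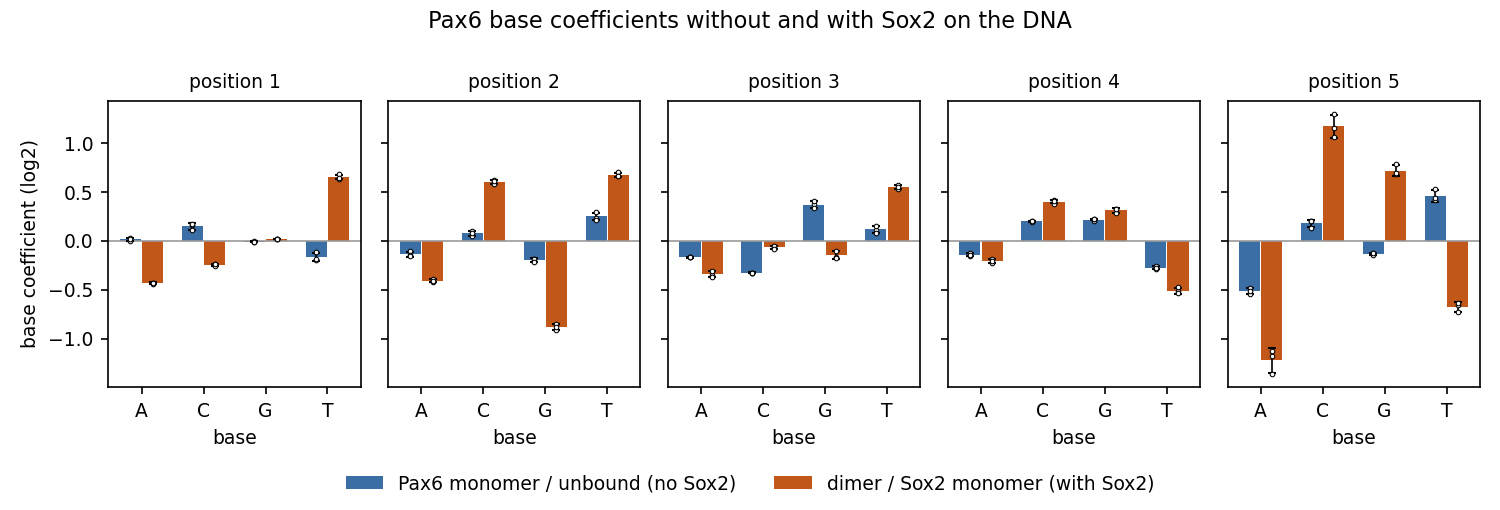
Base coefficients on a log2 scale (y axis) for each base (x axis) at positions 1 to 5, for Pax6 monomer over unbound DNA (blue) and dimer over Sox2 monomer (orange). Bars are means of 3 replicates, error bars SDs and circles the replicates. At position 5, T stands at 0.46 without Sox2 and at -0.67 with it.

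Single sequences moved in opposite directions as well, but less often than independent lists would give, and in the same direction more often. Of the 350 sequences enriched with Pax6 alone, 201 were also enriched and 121 depleted in dimer over Sox2 monomer. Of the 399 depleted with Pax6 alone, 251 were also depleted and 112 enriched. Independent lists of these sizes would share 158, 162, 185 and 180 sequences, and these comparisons use no library in common. Across sequences, which are not independent replicates, the 2 ratios had a mean Pearson r of 0.36 (Spearman rho 0.39) over 6 pairs of different replicate numbers.

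**Figure D3:**
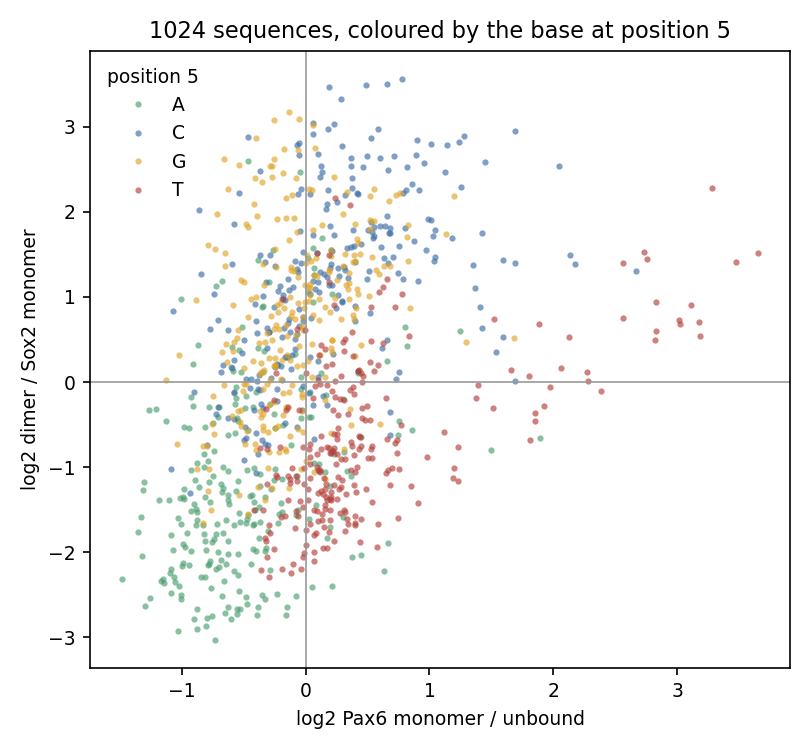
Log2 ratio of Pax6 monomer to unbound DNA (x axis) against log2 ratio of dimer to Sox2 monomer (y axis), 1 point per sequence, coloured by the base at position 5. Sequences ending in T reach 3.65 on the x axis, and sequences ending in C reach 3.56 on the y axis.

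The ratio of Pax6 monomer to unbound DNA was set against cooperativity across sequences, which are not independent replicates. With each ratio taken from another replicate, so that no library stood on both sides, the mean Pearson r was -0.12 and the mean Spearman rho -0.03 over 6 pairs, and r ranged from -0.21 to -0.07. Taken from the same replicate, r averaged -0.14. Cooperativity holds the Pax6 ratio with a minus sign, and with dimer over Sox2 monomer shuffled over the sequences the mean r from different replicates was -0.43. For Sox2 monomer over unbound DNA the mean r with cooperativity was -0.43 (rho -0.45) from different replicates, where shuffling dimer over Pax6 monomer gave -0.27. Without this built-in term, Sox2 monomer over unbound DNA had a mean r of -0.19 (rho -0.23) with dimer over Pax6 monomer and of -0.24 (rho -0.27) with dimer over unbound DNA. In all, 6 such relations were computed, with no p-value. For Sox2 monomer and cooperativity, 190 of 1000 shuffles with positions and bases permuted gave an r as low as the real one. The excess over -0.27 is therefore not told apart from the definition.

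Sequences of high G+C content were less enriched with Sox2 alone and more enriched in the dimer. Among the 512 sequences with a G+C content of 60% or more, 94 were higher and 165 lower in Sox2 monomer over unbound DNA, and 93 and 164 when adjusted over the list alone. Their mean shift against the remaining sequences was -0.17 (replicate SD 0.02, camera adjusted p = 0.00064, and adjusted p = 0.471 with an estimated correlation). In dimer over Sox2 monomer 287 were higher and 180 lower, the same numbers when adjusted over the list alone, with a shift of 0.73 (SD 0.09, camera adjusted p = 0.00017, and adjusted p = 0.471 with an estimated correlation). In cooperativity 274 were higher and 173 lower, also the same when adjusted over the list alone, with a shift of 0.50 (SD 0.13, camera adjusted p = 0.00064, and adjusted p = 0.471 with an estimated correlation). For dimer over unbound DNA the shift was 0.55 (SD 0.11, 285 higher and 184 lower, camera adjusted p = 0.00064, and adjusted p = 0.471 with an estimated correlation). For dimer over Pax6 monomer it was 0.33 (SD 0.15, 277 higher and 184 lower, camera adjusted p = 0.0069, and adjusted p = 0.556 with an estimated correlation). By position, the mean of C and G minus that of A and T in cooperativity was 1.84 (SD 0.16) at position 5 and 0.30 at position 4, but -0.37, -0.16 and -0.26 at positions 1, 2 and 3. The group did not pass for Pax6 monomer over unbound DNA (shift 0.23, SD 0.04, adjusted p = 0.10), where leaving out replicate 3 gave an adjusted p of 0.038 at the preset correlation. With an estimated correlation and all replicates it was 0.768. The remaining 512 sequences, with a G+C content of 40% or less, are the complement and have the opposite shifts, with 173 higher and 286 lower in cooperativity. The 244 sequences with at least 1 CpG did not pass in any contrast, with 112 higher and 100 lower in cooperativity both over all sequences and when adjusted over the list alone (shift 0.11, SD 0.07, adjusted p = 0.70). For Pax6 monomer over unbound DNA the mean shift of the CpG group was 0.01 while camera's direction was down (adjusted p = 0.79).

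Of the short motifs chosen beforehand, TCACC, part of the Pax6 half-site in the DC5 enhancer of the chicken delta-crystallin gene, had the highest cooperativity. Its log2 ratio was 0.13 with Pax6 alone, with an edgeR adjusted p of 0.41, and 2.54 in dimer over Sox2 monomer (adjusted p = 2.3e-15), and its cooperativity was 2.41 (adjusted p = 3.2e-11). Its bases at positions 1, 2, 4 and 5 had the highest cooperativity coefficients there (0.82, 0.52, 0.20 and 0.99), while A at position 3 had -0.17. Whether the motif adds to these single-base effects was not tested. The place of the 5 bases relative to a Pax6 site is not given in the sources used here. The reverse complement GGTGA had a cooperativity of -0.15 that did not pass (adjusted p = 0.12). CACGC, from the paired domain consensus, had a cooperativity of 0.96 and its reverse complement GCGTG one of 0.69, with edgeR adjusted p-values of 2.0e-05 and 1.5e-05.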

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

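Of the tests of technical explanations and the counts over other groupings of the libraries, those in the more abundant sequences, of cooperativity itself within classes of equal G+C count and with positions and bases permuted were chosen before their results were seen and the others only afterwards. The results below differ between DNA with and without Sox2, by the test of that difference, which is the cooperativity contrast. It equally compares DNA with and without Pax6, so it does not assign a difference to 1 of the proteins. By edgeR 906 sequences differed, and in limma 19 of 20 base coefficients. There were 121 sequences higher with Pax6 alone and lower with Pax6 where Sox2 was present, and 112 that went the other way, both below the 162 and 180 of independent lists of these sizes, while 201 were higher and 251 lower in both, above the 158 and 185 of independent lists. The coefficients of the difference at position 1 were -0.45 for A, -0.39 for C and 0.82 for T. At position 2 they were -0.27 for A, 0.52 for C, -0.68 for G and 0.43 for T. At position 3 they were -0.17 for A, 0.26 for C, -0.52 for G and 0.43 for T, and at position 4 -0.064 for A, 0.20 for C, 0.093 for G and -0.23 for T. At position 5 they were -0.71 for A, 0.99 for C, 0.85 for G and -1.13 for T. Among named sequences TCTCG (3.34), TATCC (3.34) and TTTCG (3.31) were highest, and CGTAA (-2.85), AAGCT (-2.64) and AGTAA (-2.61) lowest. Of 100 groupings of the 12 libraries, only the real one, 1 of 100, gave as many sequences (906, highest other 634). The same held for the coefficients (19, highest other 16). Any other grouping puts libraries of different bands under 1 label, so these counts show that the band labels matter. They cannot separate cooperativity from differences between single bands. With 100 groupings that keep 1 library of each band label in every replicate number, the highest other was 610 sequences and 13 coefficients.

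The opposite average preference for C and T at position 5, with and without Sox2, was weighed against 3 technical explanations. A bias of PCR by G+C content would act at every position alike, but the mean of C and G minus that of A and T in the cooperativity coefficients was -0.12 (SD 0.04) over positions 1 to 4 and 1.84 at position 5. Carry-over of unbound DNA pulls ratios towards 0, yet C minus T was 1.84 (SD 0.17) in dimer over Sox2 monomer, above the 0.22 that Sox2 monomer over unbound DNA would allow, and in the more abundant 512 sequences the cooperativity difference was still 2.03 (SD 0.21), against counting noise of rare sequences. These values argue against each of the 3 as the source of the whole difference, and do not exclude a partial share. Mixing among the bound bands was not tested. Dissociation of complexes during electrophoresis, which moves DNA from the dimer band to the monomer bands, was not tested and stays open, as does the hypothesis, not tested here, that Sox2 on the DNA changes the contacts of Pax6 with position 5.

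TCCTC and ATGCT stood above the median of their 15 single-substitution neighbours in each of the 12 libraries, by log2 3.02 to 5.30 and 1.93 to 3.84, while the highest excess of any other sequence was 2.36 for TTTTT. An uneven starting library would leave the ratios between bands unchanged, but the cooperativity of TCCTC lay at -10.5 residual SDs from the dinucleotide model. For ATGCT the same test gave -0.92 residual SDs, which an uneven library allows, and a second test, chosen after that value was seen, found that its log2 share varied between replicates of a band with an SD of 0.72 against a 99th percentile of 0.25. Extra DNA of these sequences entering the libraries stays open: their excess was among the 2 largest in 12 of 12 libraries, but they were picked by that excess, so the count decides nothing. No biological explanation was tested.

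Sequences favoured by Sox2 alone tended to have low cooperativity, with a mean r of -0.43 from replicates that share no library. Cooperativity holds the Sox2 ratio with a minus sign, which alone gave -0.27 (-0.35 to -0.19) in 1000 shuffles of the other ratio over single sequences, but sequences that share bases are not independent, and with positions and bases permuted 190 of 1000 shuffles gave an r as low as the real one, so the definition cannot be excluded as the cause. Without that term, against dimer over Pax6 monomer, the mean r was -0.19 (SD 0.05 over 6 pairs). Within classes of equal G+C count it was -0.13 (SD 0.05) with the 6 classes weighted equally (0.30 and -0.49 in those of 32 sequences, -0.18 to -0.13 in the other 4) and -0.15 (SD 0.04) weighted by size, which unlike the first met the bound against G+C content, so the answer depends on the weighting and G+C content stays open. The test first chosen gave -0.38 (SD 0.05) and met its own bound, but it used cooperativity and so holds the built-in term, and it was replaced after its result was seen; an effect of the proteins on each other and dissociation during electrophoresis were not tested.

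For the 5 other contrasts, 3 libraries against 3 give 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, gave as many calls in each. The numbers of sequences called were 548 for Sox2 monomer, 749 for Pax6 monomer and 929 for dimer over unbound DNA, 938 for dimer over Sox2 monomer and 941 for dimer over Pax6 monomer. The highest of the other splits was 0 in each with edgeR, those that like the real one part all 3 replicate numbers (4 of the 10, the real one included) among them, with at most 25 sequences at an unadjusted p under 0.05. The numbers of base coefficients were 13, 18, 19, 19 and 19, with 0 as the highest of the other splits in limma and 0 at an unadjusted p under 0.05. Any other split puts libraries of different bands under 1 label, which widens the spread within a label. The counts of 0 were thus nearly fixed in advance, and no conclusion about chance is drawn from them.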

How the results depend on the processing

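Thinning of all libraries to the smallest total and the removal of TCCTC and ATGCT were chosen after seeing the data. No sequence group, recomputed correlation or named value changed direction under any alternative run. Counts of calls were compared in size only, and the larger side of near-even splits changed in some runs. With library totals in place of TMM, 231 were higher and 332 lower for Sox2 monomer over unbound DNA, against 276 and 272 with TMM. For dimer over unbound DNA they were 412 and 520, against 469 and 460, and for dimer over Pax6 monomer 449 and 481, against 477 and 464. Of 530 recomputed values of named sequences and bases 523 kept direction and side of the threshold. The other 7 lost the call only when tested against a 2-fold change with glmTreat, the cause being the stricter null. That test called 0 sequences higher and 0 lower for Sox2 monomer over unbound DNA (edgeR, 3 at an unadjusted p under 0.05; DESeq2's test against no change called 8 with a 2-fold change). It called 56 and 7 for Pax6 monomer over unbound DNA, 212 and 226 for dimer over unbound DNA, 256 and 258 for dimer over Sox2 monomer, 149 and 213 for dimer over Pax6 monomer, and 192 and 234 for cooperativity. Leaving out 1 replicate in turn gave 156 to 272 higher and 163 to 273 lower for Sox2 monomer over unbound DNA, lowest without replicate 1. For the G+C groups in Pax6 monomer over unbound DNA it gave adjusted p-values of 0.038 to 0.154, passing without replicate 3. With an estimated correlation both G+C groups lost the call, at adjusted p = 0.471 in 4 contrasts, and at 0.556 and 0.535 for dimer over Pax6 monomer; the cause was the larger correlation assumed. The filters at 10 and 100 reads removed no sequence and say nothing about stability. Their runs are among the 530 values and were the same by construction. Without TCCTC and ATGCT, 14 base coefficients passed for Sox2 monomer over unbound DNA, 18 for Pax6 monomer and 19 in each other contrast. Library totals in place of TMM shifted the median by -0.16 for Pax6 monomer, -0.23 for dimer over unbound DNA and -0.18 for dimer over Sox2 monomer.

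With the replicate number as a block, edgeR called 288 higher and 293 lower for Sox2 monomer over unbound DNA and 449 and 462 for cooperativity. In limma A at position 1, C at position 3 and G at position 4 then passed for Sox2 monomer over unbound DNA (adjusted p = 0.048, 0.039 and 0.048), and G at position 1 for dimer over Sox2 monomer and cooperativity. The block changed no other call of a base coefficient, of a sequence named with its value as highest or lowest, of a motif chosen beforehand or of a sequence group.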

Other observations

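The values in this part were chosen after the data had been seen. GCT was set against the ratio of Pax6 alone in each of its 3 registers. All 16 sequences with GCT at positions 3 to 5 were higher in Pax6 monomer over unbound DNA, with a mean log2 ratio of 2.81 (SD 0.12, n = 3), where the model of single bases gave 1.07. They include ATGCT, whose counts stood far above those of its neighbours. With GCT at positions 2 to 4 all 16 were lower, with a mean of -0.76 (SD 0.02), where the model of single bases also gave -0.76. With GCT at positions 1 to 3 the mean was 0.16 (SD 0.03), with 8 higher and 4 lower, and the model gave 0.23.

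Of the 16 sequences ending in GCT, 12 were higher in dimer over Sox2 monomer in edgeR's test and 4 did not pass, and the mean log2 ratio, relative to the typical sequence, was 0.82 (SD 0.25, n = 3). Their cooperativity was lower in all 16, with a mean of -1.99 (SD 0.15). Cooperativity subtracts the ratio of Pax6 alone, by which these sequences were picked, so a low value was partly built in. The model of single bases gave -0.41 for dimer over Sox2 monomer and -1.48 for cooperativity. A ratio that did not depend on the orientation of the 5 bases would be equal in a sequence and its reverse complement. Across 512 pairs of a sequence and its reverse complement, which are not independent replicates, the correlation of log2 dimer over unbound DNA was -0.47, and it was -0.06 for Pax6 monomer and 0.08 for Sox2 monomer over unbound DNA.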
